A study of Gelatoporia subvermispora and Trametes versicolor with 24 samples.

How the data were processed

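RNA was measured in 2 white-rot fungi, Trametes versicolor (strain FP-101664) and Gelatoporia subvermispora (strain FP-105752), both grown as monokaryons, mycelium whose cells carry a single nuclear type. Per the labels' protocols, static cultures in a medium with 5 g/L cellobiose at 28 °C received 5 mM ascorbic acid and 1 mM α-tocopherol, and 30 min later either vanillate or the same volume of water. Vanillate, the anion of an aromatic acid with a methoxy group that is related to lignin, was given in 2 pulses 12 h apart to a final 2 mM, and mycelium was collected 12 h after the last one. T. versicolor was treated after 5 days of growth and harvested on day 6, and G. subvermispora was treated after 12 days and harvested on day 13. Libraries were made, per the labels' protocols, from DNase-treated total RNA with a stranded total RNA kit and sequenced as single reads.

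The authors deposited a table of raw read counts per gene for each of 24 libraries, with no normalization. The submitters' processing notes name FastQC, STAR and HTSeq without versions. The genome builds, annotations, counting options and the use of strand are not given in the sources used here. The tables held 14570 genes for T. versicolor and 12313 for G. subvermispora, of which 42 and 110 carried a gene symbol and the rest a locus identifier. No table pairing identifiers with names or products, and no genome, was used here, so no coordinates are given and no function is stated for an identifier. Each table closed with 5 lines of reads assigned to no gene, which were kept out of library sizes and tests. Genes took 75.4% ± 0.85 (SD, n = 3) of reads in T. versicolor water flasks and 75.5% ± 0.47 with vanillate, and 78.5% ± 1.83 and 74.1% ± 3.54 in G. subvermispora. The count of reads aligned to more than 1 place was 0 in every library. Whether such reads were instead put into the class of low alignment quality is not stated. Reads shared between near-identical copies, as in the peroxidase and laccase families, could have been lost or split, and values of those genes are uncertain. Antisense or overlapping genes could share reads as well.

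The titles give 2 libraries for each fungus, treatment and replicate number, one of them with an irregular title in T. versicolor water replicate 1. What the second library is, is not stated: the design describes 3 flasks per treatment, whereas the growth protocol speaks of 12 cultivations per fungus. The counts of these repeat libraries were compared by chi-square over genes with at least 10 counts. Within a flask, chi-square per degree of freedom was 1.015 to 1.085 in the 6 pairs of T. versicolor and 1.014 to 1.064 in the 6 of G. subvermispora. Between flasks of 1 group it was 2.311 to 8.763 and 2.884 to 8.647, over 24 pairs in each fungus. The departure from sampling noise within flasks was small, yet the chi-square test detected it in 5 of 6 pairs of each fungus. The lowest value of every library was with its own repeat, in 12 of 12 libraries of each fungus, and the best correlation across the library sets was with the own repeat in 10 of 12. The 2 libraries were therefore taken as repeats of 1 flask, summed and counted once, giving 3 flasks per group and 12 in all. Whether flasks with one label came from separate seed cultures is not stated, so p-values measure the spread between these flasks.

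Depth was 1764115 to 8143448 gene counts per library and 3950984 to 13835447 per flask in T. versicolor, and 2865064 to 7160920 and 6119420 to 12333618 in G. subvermispora. Reads carry no molecular identifiers, so counting intervals cover counting error only.

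Each fungus was fitted alone, vanillate against water, with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with its defaults (min.count 10, min.total.count 15), libraries were scaled by TMM, and the quasi-likelihood F test was two-sided with robust estimation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from this test. Levels are CPM, counts scaled to a common library total, computed here with TMM scaling and given as mean ± SD over 3 flasks. Log2 fold changes are given with a standard error (SE) derived from the test. It is the absolute log2 fold change divided by the square root of the F statistic, and can be too small at low counts. A total of 11032 genes of T. versicolor and 10318 of G. subvermispora were tested.

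These tests, the alternatives to them, 17 gene lists built from product keywords and the rule for naming genes were fixed before the data were examined. By that rule the genes named were those changed at least 2-fold without overlap between groups and with a mean CPM of at least 5 in the higher group, up to a set number in each direction. Up to 2 higher and 2 lower members of each list with at least 5 members, and the most changed genes whatever their name, were added to these. Without product names the keywords could only be matched to symbols. A single list per fungus found any member, 2 genes in T. versicolor and 4 in G. subvermispora, and neither reached the 5 needed for a set test. Families were therefore formed from shared symbols (MnP, LiP, VP and GP together, TvLac or Cslcs, HTP, CsPh, STE3, ATG, CsMn and ter) after the symbols had been seen, so they are not independent of that choice, and took the place of the lists. They were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, with an estimated correlation, and with fry, which asks whether a set's genes move one way and does not compare them with other genes, adjusted over the families of a fungus. Whether the fungi differed in a family's response was tested by a two-sided permutation of fungus labels within treatment over flask means, a test chosen after the symbols had been seen. The p-values it gave can arise only if the difference in level between the fungi is taken out first. Flasks are then not fully exchangeable, so these p-values are approximate. All 400 permutations were used, and the smallest p they can give is 0.005.

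The gene test was run on simulated counts, with 49 or 50 changed genes tested at each of 4 fold sizes in each fungus. In T. versicolor, with 10931 genes, 52% of 1.5-fold, 80% of 2-fold, 100% of 4-fold and 100% of 8-fold changes were recovered, and 8.33% of calls were false. In G. subvermispora, with 10280 genes, the shares were 79.6%, 88%, 100% and 98%, and 7.14% of calls were false. Both false shares were above the level set by the threshold. Far fewer genes were changed than were called in the data, and as many up as down, so these shares need not hold for the real calls.

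Alternatives were each repeat library alone, all libraries as separate samples, DESeq2 size factors, library totals, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a filter of CPM of at least 5 in at least 3 flasks, leaving out each flask in turn, and a block for the replicate number. Thinning all flasks to equal depth was added after seeing the data.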

Results

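The series profiled RNA from T. versicolor and G. subvermispora, fungi that degrade lignin in wood, after 2 pulses of vanillate or of water. It concerned how white-rot fungi break down methoxylated compounds related to lignin. For each fungus 3 vanillate flasks were compared with 3 water flasks, each flask being the sum of 2 repeat libraries that differed far less from each other than from other flasks. Flask totals were 3950984 to 13835447 gene counts in T. versicolor and 6119420 to 12333618 in G. subvermispora. On the first principal component of log2 CPM, which held 80.7% of the variance in T. versicolor and 80.8% in G. subvermispora, all vanillate flasks lay on one side and all water flasks on the other.

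In T. versicolor, the largest changes with vanillate were increases of genes named only by an identifier. TRAVEDRAFT_50755 rose from 1.40 ± 0.96 CPM to 6396 ± 583.5 CPM (SD, n = 3), a log2 fold change of 12.44 (SE 0.26, adjusted p = 6.29e-15), on 27 counts in the water flasks and 116624 in the vanillate flasks. TRAVEDRAFT_50760 rose from 0.39 ± 0.13 CPM to 1029 ± 301.8 CPM, a log2 fold change of 11.22 (SE 0.34, adjusted p = 3.34e-10), on 10 and 18546 counts. By counting error alone, the 95% interval of the ratio of vanillate to water was 3900 to 8620 for TRAVEDRAFT_50755. For TRAVEDRAFT_50760 it was 1330 to 5090, and both intervals are wider than these SEs imply. The largest falls were smaller, at -2.66 (SE 0.30) for TRAVEDRAFT_86322 and -2.43 (SE 0.21) for TRAVEDRAFT_152872, with adjusted p of 1.68e-05 and 1.96e-05. The 110 genes that rose at least 8-fold took 0.0984% ± 0.00402 of gene counts in water and 5.75% ± 0.544 with vanillate, a share that was bound to rise because the genes were chosen for rising.

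Of 11032 genes tested in T. versicolor, 2222 rose and 2042 fell, together 38.7%. At least 2-fold changes were mostly increases, with 764 genes higher and 211 lower, so that 78.4% of them were higher. Genes at least 2-fold higher had a median of 3.51 CPM in water, against 29.7 CPM over all genes tested and 90.3 CPM for genes at least 2-fold lower. Choosing genes for rising favours low levels in water. With vanillate the median of the higher genes was 12.7 CPM, still under the 29.7 CPM of all genes in water. Among the 6428 genes with a mean of at least 20 CPM, 270 were at least 2-fold higher and 146 lower, or 64.9% higher. The 3 flasks of each group did not overlap in 50.1% of genes, where chance gives 10%.

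**Figure D1:**
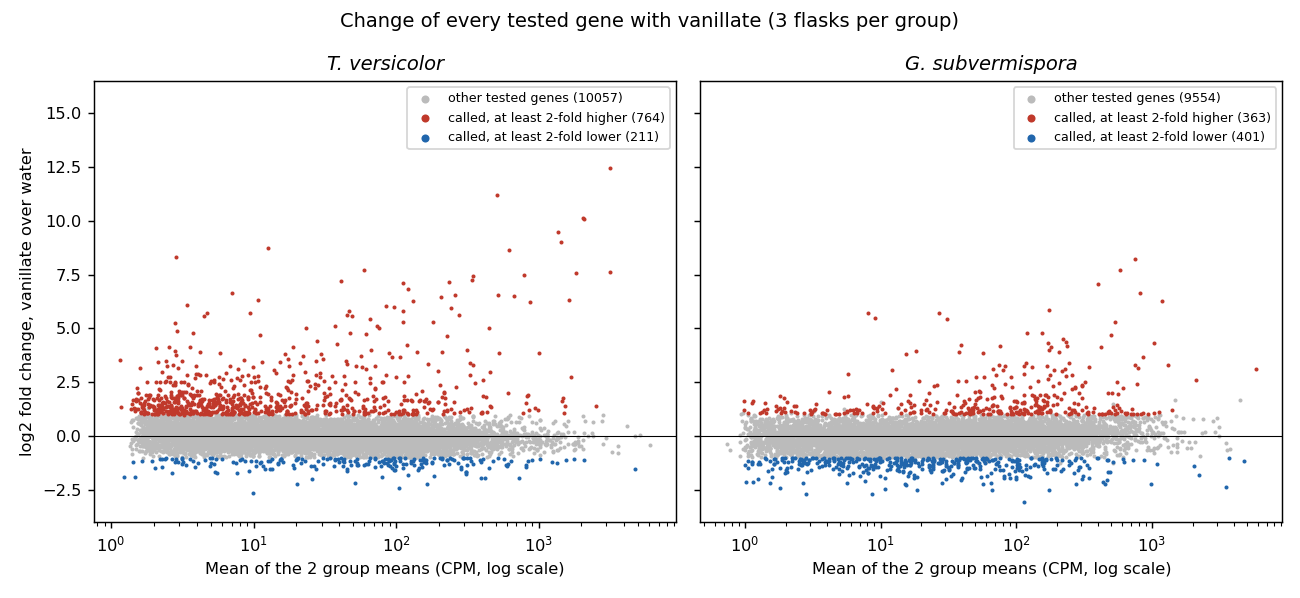
Each point is a tested gene, with the mean of the water and vanillate levels (CPM, log scale) on the horizontal axis and the log2 fold change of vanillate over water on the vertical axis, from 3 flasks per group. Red points are the 764 genes of T. versicolor and 363 of G. subvermispora called at least 2-fold higher, blue points the 211 and 401 called at least 2-fold lower, and grey points all others; in both fungi the largest changes were increases.

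Among genes of T. versicolor with a symbol, 6 of 40 rose and 4 fell. The laccase TvLac7 changed most: it rose from 2.73 ± 0.46 to 32.3 ± 9.57 CPM, a log2 fold change of 3.60 (SE 0.26, adjusted p = 1.96e-07). Laccases are copper oxidases of phenols, and of the 7 tested TvLac7 was the 1 that rose while the other 6 did not pass. Without water replicate 2, and likewise with a block for the replicate number, the counts were 1 higher and 1 lower. The most abundant of these, TvLac1, stood at 264.1 ± 121.9 CPM in water and 161.4 ± 73.0 CPM with vanillate (adjusted p = 0.322). The laccases as a set did not pass camera (adjusted p = 0.984), with a median log2 fold change of -0.13 and a mean of 0.33 that differed in sign.

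Class II peroxidases are the secreted heme enzymes of white-rot fungi that attack lignin, comprising manganese (MnP), lignin (LiP) and versatile (VP) peroxidases. Of 24 tested in T. versicolor, 4 rose, 3 fell and 17 did not pass, and adjusted over the list alone 3 rose and 2 fell. All 4 that rose were low: a filter of CPM of at least 5 in at least 3 flasks left them out, and of the 8 then tested 0 rose and 3 fell. With the first library alone 0 of 11 rose and 2 fell. The DESeq2 Wald test gave 2 higher and 2 lower, and a replicate block 5 and 3. The counts rest on few flasks: 2 rose and 1 fell without vanillate replicate 1, 3 rose and 1 fell without water replicate 2, and 2 rose and 4 fell without water replicate 3. VP1 rose by a log2 fold change of 1.65 (SE 0.34, adjusted p = 0.00131), from 1.72 ± 1.14 to 5.13 ± 0.62 CPM. MnP5s rose by 1.16 (SE 0.31, adjusted p = 0.00716), a call that was lost without water replicate 2 (0.78, adjusted p = 0.088). LiP1 fell from 17.8 ± 5.32 to 10.0 ± 0.78 CPM (log2 fold change -0.81, SE 0.20, adjusted p = 0.00438). MnP1s fell by 0.63 on the log2 scale (SE 0.23, adjusted p = 0.0426), and this call was lost without water replicate 1 or 2 or vanillate replicate 1 or 2 (adjusted p = 0.0932, 0.0727, 0.0805 and 0.135). The remaining calls, MnP4s and MnP12s as higher and MnP11s as lower, were lost without vanillate replicate 1 (adjusted p = 0.0942, 0.177 and 0.0708) and, 1 or more of them, without any other flask; these 3 were chosen after their values were seen. VP2, the most abundant of the family, was at 125.3 ± 29.2 CPM in water and 96.0 ± 15.7 CPM with vanillate (adjusted p = 0.0957). The set did not pass camera (adjusted p = 0.984), and its median log2 fold change was 0.00, a value that was below 0 with library totals (-0.03) and with DESeq2 size factors (-0.003).

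Of the other symbols of T. versicolor, the 3 heme-thiolate peroxidases (HTP) did not pass, with log2 fold changes of -0.38, 0.48 and 0.34 for HTP1, HTP2 and HTP3 and unadjusted p of 0.0887, 0.0342 and 0.236. The cytochrome c peroxidase gene CCP1, whose product removes hydrogen peroxide in mitochondria, rose from 186.1 ± 10.5 to 232.5 ± 12.9 CPM (log2 fold change 0.32, SE 0.09, adjusted p = 0.00942). Without vanillate replicate 1 its adjusted p was 0.0573. The preset list of secreted lignin-modifying enzymes held the dye-decolorizing peroxidases DyP1 and DyP2. DyP1 fell (log2 fold change -0.69, SE 0.18, adjusted p = 0.00746, and 0.0517 without vanillate replicate 3), and DyP2 was 0.54 (SE 0.22, adjusted p = 0.0662). Adjusted over the list alone, 1 rose and 1 fell. CCP1 was chosen for the text after its values were seen.

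In G. subvermispora the genes that rose most were again identifiers without a name, while 9 of 15 class II peroxidases fell. CERSUDRAFT_157295 rose from 4.91 ± 0.33 to 1484 ± 66.0 CPM (SD, n = 3), a log2 fold change of 8.23 (SE 0.10, adjusted p = 1e-15), on 138 and 40134 counts. CERSUDRAFT_116559 rose from 5.44 ± 0.72 to 1152 ± 473 CPM (log2 fold change 7.72, SE 0.47, adjusted p = 0.00018). CsPh12 fell from 202.8 ± 15.8 to 24.5 ± 1.58 CPM, a log2 fold change of -3.06 (SE 0.08, adjusted p = 2.22e-12), and CERSUDRAFT_80123 had the next largest fall, -2.68 (SE 0.25, adjusted p = 2.03e-06). The 48 genes that rose at least 8-fold took 0.288% ± 0.0101 of gene counts in water and 3.57% ± 0.301 with vanillate, again genes chosen for rising.

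Of 10318 genes tested in G. subvermispora, 2629 rose and 2675 fell, together 51.4%, and with library totals in place of TMM 1788 rose and 3812 fell. At least 2-fold changes were divided between 363 higher and 401 lower genes, 47.5% of them higher. With library totals the division was 265 and 610, or 30.3% higher, and the median of all genes was -0.137 on the log2 scale, against -0.011 with TMM. The groups did not overlap in 59.2% of genes, where chance gives 10%. Among genes with a symbol, 18 of 106 rose and 45 fell.

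Of 15 class II peroxidases tested in G. subvermispora, 9 fell, 1 rose and 5 did not pass, and the counts adjusted over the list alone were the same. LiP2 fell from 450.4 ± 24.3 to 96.5 ± 6.07 CPM (log2 fold change -2.23, SE 0.07, adjusted p = 2.1e-11). MnP2, the most abundant, fell from 750.0 ± 74.2 to 183.9 ± 8.02 CPM (-2.03, SE 0.08, adjusted p = 1.81e-10). MnP10 and MnP6 also fell, with log2 fold changes of -1.25 and -1.12. MnP4 rose by 0.55 (SE 0.21, adjusted p = 0.0378), on 107 counts in water and 150 with vanillate, and the call was lost without water replicate 2 or 3 or vanillate replicate 1 or 2 (adjusted p = 0.0959, 0.0982, 0.134 and 0.0557) and with library totals (0.0942). The family's median log2 fold change was -0.45 and it passed camera as lower (adjusted p = 0.0124), but not with an estimated correlation (adjusted p = 0.2 with an estimated correlation). MnP10 and MnP6 were chosen after their values were seen.

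**Figure D2:**
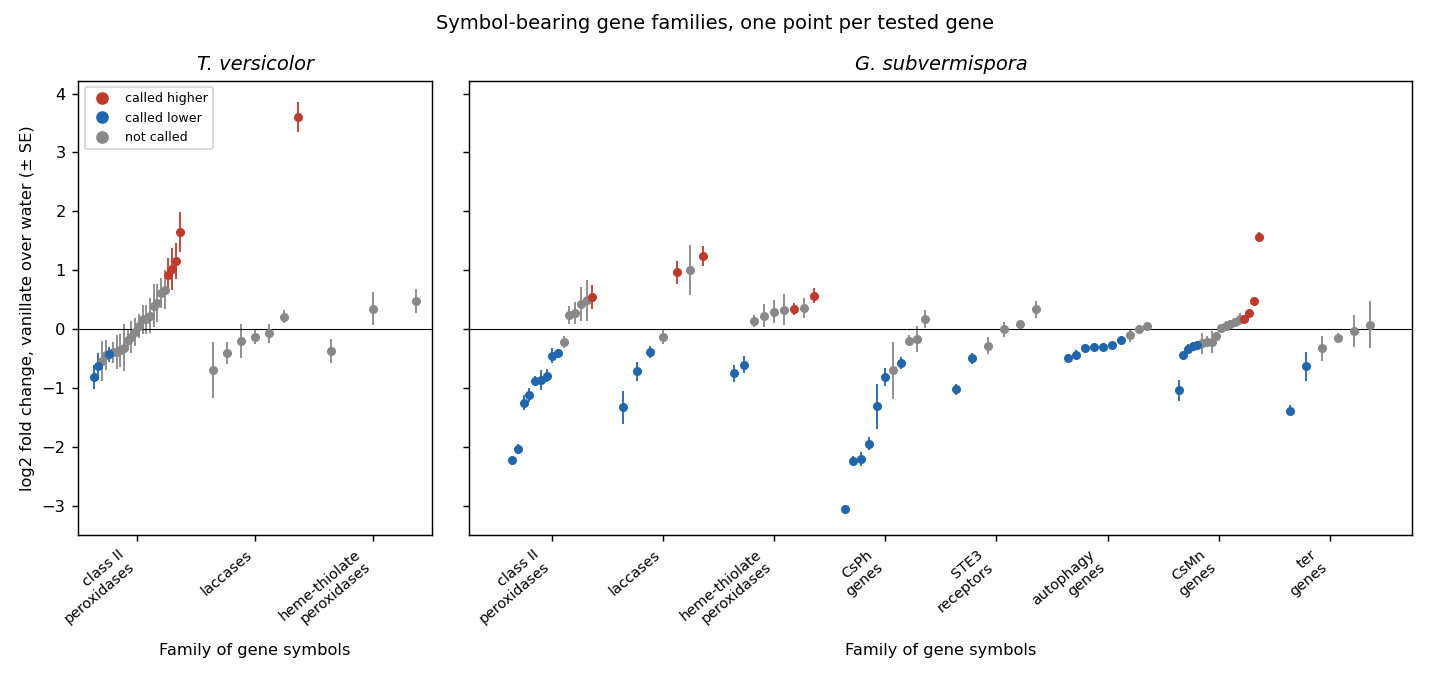
Each point is a tested gene of a symbol family, with its log2 fold change of vanillate over water and SE (bars), in T. versicolor on the left and G. subvermispora on the right; red genes were called higher, blue genes lower and grey genes not called. Of the class II peroxidases 9 of 15 fell in G. subvermispora, and 4 of 24 rose and 3 fell in T. versicolor, where without vanillate replicate 1 the counts were 2 and 1.

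The CsPh genes, whose function is not stated in the sources used here, had the lowest median log2 fold change among the families of G. subvermispora. Of 11 tested 7 fell and 4 did not pass, also adjusted over the list alone, with a median log2 fold change of -0.81. CsPh2 fell from 1620 ± 129.3 to 344.6 ± 13.9 CPM (-2.23, SE 0.08, adjusted p = 5.24e-11), CsPh3 from 747.2 ± 127.7 to 161.3 ± 11.3 CPM (-2.21, SE 0.12, adjusted p = 1.7e-07), and CsPh5 fell by 1.94 on the log2 scale (SE 0.10, adjusted p = 2.49e-08). The family passed camera as lower (adjusted p = 0.00155), though not with an estimated correlation (adjusted p = 0.2 with an estimated correlation).

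The laccases of G. subvermispora moved both ways: 2 of 7 rose, 3 fell and 2 did not pass, also adjusted over the list alone. Cslcs7 rose from 14.8 ± 1.51 to 35.3 ± 8.03 CPM (log2 fold change 1.24, SE 0.17, adjusted p = 0.000126) and Cslcs3 rose by 0.97 (SE 0.20, adjusted p = 0.00104). Cslcs2 fell from 193.6 ± 63.3 to 76.6 ± 9.89 CPM (-1.33, SE 0.28, adjusted p = 0.0143, and 0.0524 without vanillate replicate 2), and Cslcs5 fell by 0.72 on the log2 scale (SE 0.16, adjusted p = 0.00204). The most abundant, Cslcs1, was at 506.6 ± 247.1 CPM in water and 1013 ± 241.6 CPM with vanillate, and its adjusted p was 0.121. The set did not pass camera (adjusted p = 0.992), and its median of -0.13 and mean of 0.09 differed in sign.

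PRX5 and CCP of G. subvermispora, whose symbols are those of enzymes that remove peroxides, both rose. PRX5, by its symbol a peroxiredoxin, rose from 295.8 ± 31.2 to 809.6 ± 55.8 CPM (log2 fold change 1.45, SE 0.09, adjusted p = 1.02e-08). CCP, by its symbol a cytochrome c peroxidase, rose from 213.2 ± 9.11 to 531.4 ± 27.7 CPM (1.32, SE 0.07, adjusted p = 2.78e-09). Of the 9 heme-thiolate peroxidases, secreted enzymes that transfer oxygen from peroxide to organic compounds, 2 rose, 2 fell and 5 did not pass, also adjusted over the list alone. HTP7 rose by 0.57 (SE 0.13, adjusted p = 0.00558) and HTP1 by 0.34 (SE 0.10, adjusted p = 0.0169), while HTP4 and HTP3 fell, with log2 fold changes of -0.75 and -0.60 (adjusted p = 0.000703 and 0.00266). The call of HTP1 was lost without water replicate 1 or 2 or vanillate replicate 2 or 3 (adjusted p = 0.0535, 0.0635, 0.068 and 0.0668) and with library totals (0.21, adjusted p = 0.0796). The set did not pass camera (adjusted p = 0.473).

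**Figure D3:**
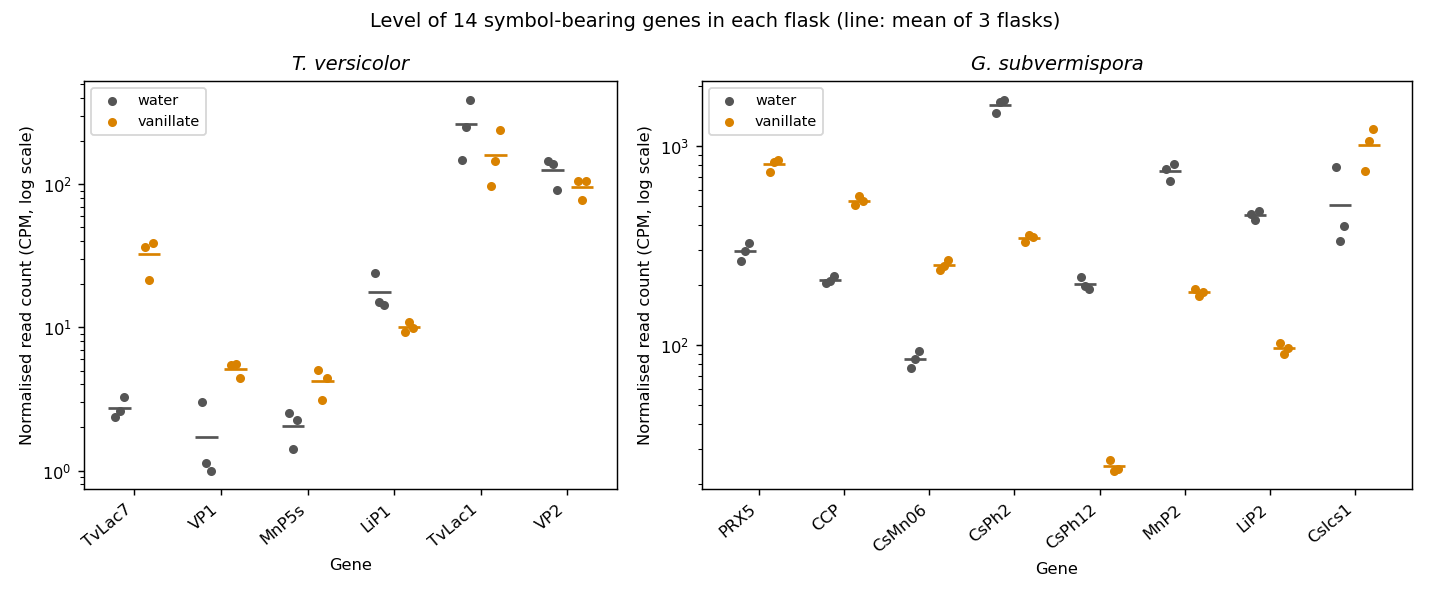
Points are the levels of 14 genes in each of 3 water (grey) and 3 vanillate (orange) flasks, in CPM on a log scale, with a line at each mean; T. versicolor is on the left and G. subvermispora on the right. TvLac7 rose from 2.73 to 32.3 CPM, MnP2 fell from 750.0 to 183.9 CPM, and the flasks of TvLac1, VP2 and Cslcs1 overlapped between groups.

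Of the 10 autophagy genes (ATG), which serve the breakdown of a cell's own contents, 7 fell and 3 did not pass, also adjusted over the list alone, each by a small amount. ATG15B fell from 100.7 ± 9.90 to 71.3 ± 4.67 CPM (log2 fold change -0.50, SE 0.08, adjusted p = 0.000138) and ATG15A fell by 0.43 on the log2 scale (SE 0.07, adjusted p = 0.000172). The family passed camera as lower at a median of -0.29 (adjusted p = 0.0408), but with an estimated correlation the value was 0.2 (adjusted p = 0.2 with an estimated correlation). It was 0.0589 without water replicate 3, 0.0564 without vanillate replicate 1, 0.065 with the first library of each flask, 0.05 at equal depth and 0.217 with the DESeq2 Wald test.

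Of the 6 STE3 genes, which encode pheromone receptors, CsSTE3.2 fell from 54.5 ± 2.78 to 26.9 ± 2.76 CPM (-1.02, SE 0.09, adjusted p = 6.56e-07), CsSTE3.3 fell by 0.50 on the log2 scale (SE 0.09, adjusted p = 0.000334) and 4 did not pass, also adjusted over the list alone. The STE3 counts were 1 higher and 3 lower without water replicate 1, 1 and 2 without vanillate replicate 3, and 0 and 3 with library totals. Of 18 CsMn genes 4 rose, 5 fell and 9 did not pass, with the same counts adjusted over the list alone. With library totals 2 rose and 7 fell, and on leaving out a flask 3 to 5 rose and 5 or 6 fell. CsMn06 rose from 84.9 ± 8.17 to 252.3 ± 15.4 CPM (1.57, SE 0.08, adjusted p = 1.79e-09) and CsMn41 by 0.48 (SE 0.07, adjusted p = 3.34e-05). CsMn38, at 4972 ± 1155 CPM in water, fell to 2419 ± 368.1 CPM (-1.04, SE 0.18, adjusted p = 0.00216), and CsMn01 fell by 0.45 on the log2 scale (SE 0.07, adjusted p = 0.000168). Of 6 ter genes 2 fell and 4 did not pass, and 1 fell adjusted over the list alone. ter14 fell from 43.7 ± 2.55 to 16.6 ± 1.21 CPM (-1.39, SE 0.10, adjusted p = 5.12e-08), and ter9 fell by 0.63 on the log2 scale (SE 0.25, adjusted p = 0.0456), a call lost on leaving out any flask (adjusted p = 0.0563 to 0.16). Outside the families, acl4 fell from 66.7 ± 6.41 to 23.6 ± 1.35 CPM (-1.49, SE 0.09, adjusted p = 1.63e-08). The STE3, CsMn and ter sets did not pass camera (adjusted p = 0.473, 0.992 and 0.121), though the ter set did without vanillate replicate 3 (adjusted p = 0.0429). By fry, the class II peroxidases (adjusted p = 4.11e-06), CsPh (0.000208), autophagy (0.000208), ter (0.0184) and STE3 (0.0427) sets of G. subvermispora passed as lower, and its heme-thiolate peroxidases (0.0932), laccases (0.191) and CsMn genes (0.216) did not, nor did the laccases (0.39) and class II peroxidases (0.456) of T. versicolor. Camera passed none of these sets when the correlation was estimated: adjusted p = 0.2 with an estimated correlation for the class II peroxidases, CsPh and autophagy sets of G. subvermispora, 0.625 for ter, 0.806 for STE3, 0.625 for heme-thiolate peroxidases and 0.992 for laccases and CsMn, and 0.985 for both sets of T. versicolor.

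The preset list of membrane transporters held 4 genes of G. subvermispora, of which 2 rose and 2 fell, also adjusted over the list alone. mfs3 rose by 0.74 (SE 0.13, adjusted p = 0.000396) and mfs1 by 0.69 (SE 0.09, adjusted p = 1.79e-05), from 120.8 ± 10.2 to 194.6 ± 21.4 CPM for the latter. mfs2 and mfs4 fell, with log2 fold changes of -0.42 and -0.36 (SE 0.08 and 0.06, adjusted p = 0.000398 and 0.000287).

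The responses of the fungi were compared for 4 groups of symbols they share, as means over the genes of a group in each flask, which are not pairs of equivalent genes. Class II peroxidases moved by 0.11 in T. versicolor and by -0.57 in G. subvermispora on the log2 scale, a difference of -0.68 (permutation p = 0.005, adjusted p = 0.01). The 0.11 of T. versicolor is a mean over genes, and the family's median was 0.003 over 24 genes. That median depended on the low members: with CPM of at least 5 in at least 3 flasks it was -0.284 over 8 genes. The mean with that filter is not given here. In G. subvermispora the median was then -0.83 over 12 genes, and the difference was not tested with that filter. Cytochrome c peroxidase rose by 0.32 and 1.32, a difference of 1.00 (permutation p = 0.005, adjusted p = 0.01). For laccases the difference was -0.19 (permutation p = 0.27, adjusted p = 0.36), and for heme-thiolate peroxidases -0.03 (permutation p = 0.855). The smallest p the permutations can give is 0.005. The fungi were treated after 5 and 12 days of growth, so species and culture age cannot be separated here.

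The share of reads that aligned with low quality was higher in every vanillate flask of G. subvermispora, at 8.35% ± 3.47 against 4.61% ± 0.84 in water (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 flasks allow). Vanillate flask 1 stood highest at 12.34%. In T. versicolor the share was 2.28% ± 0.04 with vanillate and 2.07% ± 0.05 in water, and the share of reads outside annotated genes was 6.96% ± 0.07 and 6.46% ± 0.12 (exact permutation p = 0.1 for both). In G. subvermispora the latter share was 6.11% ± 0.22 with vanillate and 7.22% ± 0.17 in water (exact permutation p = 0.1).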

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

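The test of library scaling in T. versicolor, both tests on the MnP, LiP and CsPh genes of G. subvermispora and the tests of a difference between the fungi were chosen only after the result was seen.

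The response to vanillate differed between the fungi in 2 of 4 groups of symbols. The difference, G. subvermispora minus T. versicolor, was -0.677 on the log2 scale for class II peroxidases and 0.996 for cytochrome c peroxidase. No explanation was tested, since the fungi also differed in culture age and, for class II peroxidases, in the levels of the members tested.

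Some classes of reads assigned to no gene separated the groups, while the share assigned to genes overlapped between groups in both fungi. In T. versicolor the share outside annotated genes was higher in every vanillate flask by a mean of 0.5 percentage points, the share overlapping more than 1 gene by 0.07 and the share of low alignment quality by 0.21. In G. subvermispora the share of low alignment quality was higher by 3.74 percentage points, and the share outside annotated genes was lower in every vanillate flask, at 6.11% against 7.22% in water.

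In T. versicolor, genes changed at least 2-fold were mostly higher with vanillate (78.4%). The choice among TMM, size factors and library totals does not account for it, since the lowest share over them was 76%. The 3 scalings gave nearly the same median of all genes (0.001, -0.005 and -0.032 on the log2 scale), so the share could hardly move. An error shared by all 3 would not show. The share was 74.9% with all flasks at equal depth, which argues against depth, and 74.7% among genes with a CPM of at least 5 in at least 3 flasks, which leaves genes near the floor open, because 228 of the 542 higher genes that passed this filter had a mean under 5 CPM in water. A higher background of reads over all genes in the vanillate flasks, as the larger share outside genes may hint, remains open for part of it: genes between 0.1 and 1 CPM had a median log2 fold change of 0.35 (0.04 in G. subvermispora), and among genes with a mean of at least 20 CPM the share of higher genes was 64.9%, between the bounds of 60% and 70% set for that test. A response to vanillate of genes that are little used in water, a reading drawn from these same data, is left open as well.

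In G. subvermispora, CsPh12, CsPh2, CsPh3, LiP2 and MnP2 fell at least 4-fold. Dilution by strongly induced genes would lower all genes alike, but the median of all genes with library totals was -0.137. Each of these 5, chosen for their fall, was at -2.16 or lower. If loss of reads to low alignment quality were the cause, vanillate flask 1, with the most such reads, should hold the lowest levels, and its mean log2 CPM of these genes differed from the other vanillate flasks by 0.026 (SD 0.14 over genes). At nearly equal shares, 5.98% in vanillate flask 2 and 5.57% in water flask 3, the 5 genes differed by -3.02 to -2.20 on the log2 scale. That pair decides nothing, since the 5 were chosen for falling in these same flasks. A lower transcript level under vanillate may be considered, as a hypothesis from the same data.

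Of the 10 splits of 6 flasks into 3 and 3, only 1, the real one, gave as many genes in each of the 4 counts of each fungus, and 10 splits are too few for a share under 0.05. The real counts in T. versicolor were 2222, 2042, 764 and 211 for genes higher, lower, at least 2-fold higher and at least 2-fold lower, and in G. subvermispora 2629, 2675, 363 and 401. The highest of the other splits was 0 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with up to 387 and 215 genes at an unadjusted p under 0.05 against 5222 and 5897 in the real splits. Each other split puts vanillate and water flasks into both groups, so the difference between treatments widens the spread within groups. Few calls were bound to come from them, and the 0 does not measure what unrelated flasks would give.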

How the results depend on the processing

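Equal depth and all tests of families, including the estimated correlation and fry, were chosen only after the data were seen; the other alternatives were planned. The counts of T. versicolor stayed within 1.5 times in 72 of 72 alternatives and those of G. subvermispora in 71 of 72. The exception was the genes at least 2-fold lower in G. subvermispora, 610 with library totals against 401, with a median of all genes of -0.137 on the log2 scale against -0.011 with TMM. Genes higher and lower there were 1788 and 3812 with library totals, against 2629 and 2675. These counts stayed within 1.5 times, yet the balance between directions depended on the scaling. Where a named gene was tested, it kept direction and call in 148 of 156 alternatives in T. versicolor and 530 of 555 in G. subvermispora. The other 8 and 25 kept direction and lost the call. Alternatives whose filter left the gene out are not counted. On leaving out a flask, 5 to 8 of the 10 called symbols of T. versicolor and 55 to 60 of the 63 of G. subvermispora kept their call.

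The median of class II peroxidases in T. versicolor, 0.00, turned negative under many settings: -0.342 with the first and -0.09 with the second library, -0.255 with all 12 libraries as separate samples, with or without the library set as a term, -0.003 with size factors, -0.03 with library totals and with limma-voom, -0.012 without a filter, -0.284 with the stricter filter and -0.029 at equal depth. It ran from -0.147 to 0.108 on leaving out a flask. Members lie on both sides of 0, and fewer low genes were tested under the lowest of these values; for the rest the cause was not tested. In G. subvermispora the laccase median was 0.025 with the first library, and that of CsMn genes 0.015 without a filter and -0.058 to 0.036 on leaving out a flask; the cause was not tested.

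Replicate numbers did not pair flasks: deviations of same-numbered flasks correlated at -0.01, 0.1 and -0.04 in T. versicolor and at -0.03, 0.03 and -0.14 in G. subvermispora, and not every flask correlated best with its own number. With a replicate block the counts were 2238, 2069, 777 and 207 in T. versicolor and 2522, 2553, 362 and 397 in G. subvermispora. Of the named genes ter9 was no longer called with the block (adjusted p = 0.0566), and 1 laccase of T. versicolor was called lower.

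Depth limits which genes were tested: VP1 and MnP5s, on 38 and 44 counts over the water flasks, were left out by the filter with the first library alone. They were also left out with the stricter filter, and MnP5s with all 12 libraries as separate samples. The stricter filter left out MnP4, Cslcs3 and ter9 of G. subvermispora as well.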

Other observations

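The tests of a relation between abundance and change were chosen only after the result was seen, and so were the other genes named here.

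Other genes of G. subvermispora with a symbol also changed. The TOR kinases, which couple growth to nutrients, moved apart: TOR1 rose by 0.42 (SE 0.08, adjusted p = 0.000716) and TOR2 fell by 0.35 on the log2 scale (SE 0.07, adjusted p = 0.000568), in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. a2-1 fell from 261.8 ± 12.8 to 134.6 ± 7.49 CPM (SD, n = 3; adjusted p = 5.77e-08), pab1 rose from 65.2 ± 5.04 to 92.6 ± 6.97 CPM (adjusted p = 9.72e-05) and nps1 fell from 49.2 ± 2.48 to 35.9 ± 2.55 CPM (adjusted p = 0.000519). The 3 flasks of each group did not overlap for these 5 genes. Unlike nps1, nps2 rose by 0.31 (SE 0.10, adjusted p = 0.0192). That call was lost with library totals (adjusted p = 0.126) and on leaving out some of the flasks. The ferroxidase Csfet3, of iron uptake, rose by 0.31 (SE 0.08, adjusted p = 0.00526), though not with library totals (0.18, adjusted p = 0.0552), and its T. versicolor counterpart by symbol, TvFet3A, was -0.03 (SE 0.18, adjusted p = 0.916); the difference was not tested.

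In both fungi the more abundant class II peroxidases tended to have the lower log2 fold changes and the rarer ones the higher. Not every member followed this, and in T. versicolor 17 of 24 did not pass. Across genes, which are not independent replicates, Spearman's rho between mean log2 CPM and log2 fold change was -0.55 in T. versicolor (24 genes, permutation p = 0.00676) and -0.80 in G. subvermispora (15 genes, permutation p = 0.00048), with 0.00676 and 0.00096 after adjustment over these 2 relations. Pearson's r was -0.42 (permutation p = 0.0415) and -0.88 (permutation p = 3e-05), and -0.37 and -0.74 without the 2 genes farthest from the median level, VP2 and MnP11s in one and MnP2 and LiP2 in the other. A trend of abundance shared by all genes is argued against, as 2.39% of 10000 random lists matched on abundance had a rho as low in T. versicolor and 0% in G. subvermispora, where median rho was -0.17 and 0.13. The most abundant member in T. versicolor, VP2, did not itself pass (adjusted p = 0.0957), and reads shared between near-identical copies remain untested.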
